A study of Homo sapiens with 18 samples.

How the data were processed

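Polyadenylated RNA was sequenced from 3 human cell lines transfected with plasmid DNA, as 18 libraries made with a strand-marking kit, per the labels' protocols. HEK293A (embryonic kidney) and HepG2 (liver) cells received 100 ng plasmid per well by lipid transfection, and SH-SY5Y (neuroblastoma) cells were nucleofected. In each line, 3 libraries came from cells given a plasmid for the green fluorescent protein mNeonGreen (control) and 3 from cells given a plasmid for mNeonGreen and the miRNA EXACT1. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

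The authors deposited 1 table of whole-number counts per Ensembl gene ID for all 18 libraries, with no normalization. Per the submitters' processing notes, cutadapt, HISAT2, StringTie, edgeR and limma were used with the human build GRCh38 (hg38), and their versions, settings and the strand setting of the counting are not given in the sources used here. The table had 60612 rows, of which 60401 matched a gene symbol by ID. The other 211 kept their ID. No row lacked an ID. Library totals lay between 48475715 and 64714716 counts in HEK293A, between 70897097 and 77100150 in HepG2 and between 66056962 and 72587614 in SH-SY5Y. Over the 18 pairs of libraries within a group, the chi-square statistic per gene lay between 19.2 and 1201, far above sampling noise, so each library was counted as 1 replicate.

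The counts of each line were tested alone with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries scaled by TMM, and EXACT1 compared with control by the robust quasi-likelihood F test, two-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 fold changes are EXACT1 over control, with the standard error (SE) from the test. CPM of tested genes are relative to TMM-scaled library sizes, and CPM in comparisons between lines are relative to library totals. Gene positions, transcript lengths and 3' UTRs came from GENCODE release 29 on GRCh38.

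Hand-written lists of genes were tested with camera (limma 3.58.1) on voom log2 CPM at a preset correlation of 0.01, and again with an estimated correlation and with fry. There were 28 lists with 857 entries, of which 856 matched an ID. They covered miRNA biology, antiviral and stress responses, metabolism, cell division, housekeeping complexes and cell type markers, and lists with under 5 tested members were not tested. A list was called at an adjusted p under 0.05 over the lists of a line. Whether camera with an estimated correlation, or fry, could call a list with so few libraries was not tested. Their lack of calls therefore does not by itself count against a list. To look for sequence-dependent lowering without assuming a seed, log2 fold changes were regressed, for each of the 16384 words of 7 bases, on presence of the word in the longest annotated 3' UTR of at least 30 bases, with log UTR length and GC content as covariates. This regression runs over genes, which are not independent replicates, and is descriptive.

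The tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took, per line, called genes whose libraries did not overlap between plasmids and whose mean CPM was at least 1, up to 10 per direction. Where fewer than 5 genes were called, it added the 5 genes with the smallest p, said not to pass. It also took up to 4 called members of each list, and always AGO2, DICER1 and a gene that is not reported here. Other genes appear as examples of their list by abundance or because an alternative called them, and those were chosen after their values were seen.

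Alternatives were DESeq2 1.42.0, limma voom with sample weights, 2 other scalings in edgeR, no filter, a mean CPM of at least 5, an absolute log2 fold change of at least 1, a replicate block, a fit of all 18 libraries, and each library left out in turn. HEK293A values did not match the gene IDs of their rows. For that reason the HEK293A gene lists, the HEK293A named genes and the tests over 3 lines were not run. Tests of the mean change over HepG2 and SH-SY5Y and of the difference between them, in 1 edgeR fit of 12 libraries, took their place and were chosen after seeing the data. The fits without HepG2 EXACT1 replicate 1 or SH-SY5Y control replicate 2 are given beside each result because these libraries lay far from their groups. Singling them out was also a choice made after seeing the data. Levels of mNeonGreen and of EXACT1 itself were not analysed here.

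The gene test was tried on simulated counts drawn from the real means, library sizes and spread estimated per gene. In them 200 genes were changed 2-fold or 4-fold, and a planted list of 40 other genes 1.5-fold. These 40 were not counted as unchanged. With 6 libraries in HepG2 and SH-SY5Y, the deviation of the outlying library thus entered as noise independent between libraries and genes. In HepG2 the test recovered 0.0% of 100 genes changed 2-fold and 14.0% of 100 changed 4-fold among 16566 genes with 6 libraries, and 80.0% and 95.0% among 17182 genes with 5 libraries, without EXACT1 replicate 1. In SH-SY5Y it recovered 0.0% and 20.0% among 19202 genes with 6 libraries, and 68.0% and 94.0% among 19927 genes with 5 libraries, without control replicate 2. In HEK293A it recovered 45.0% and 80.0% among 21435 rows. Unchanged genes called in these simulations numbered 13 in HEK293A, 0 in HepG2 and 0 in SH-SY5Y with 6 libraries, and 20 and 21 with 5 libraries in HepG2 and SH-SY5Y. For the word regression, a 7-base word with a log2 change of -0.2 was planted in real fold changes shuffled over genes. With 6 and 5 libraries, the planted words were present in 867 and 758 genes in HepG2 and in 1136 and 515 in SH-SY5Y. They were recovered in both lines. The adjusted p was 4.34e-14 with 6 and 1.52e-14 with 5 libraries in HepG2, and 1.94e-15 with 6 and 8.20e-06 with 5 libraries in SH-SY5Y. Rarer words were not planted. Correlations were computed in R. Word tests ran under Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots used matplotlib 3.10.9.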

Results

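Gene expression was measured by RNA sequencing in HEK293A, HepG2 and SH-SY5Y cells that carried a plasmid for mNeonGreen alone or for mNeonGreen and the miRNA EXACT1, with 3 libraries per group. The series concerns a self-regulating gene therapy in a mouse model of Rett syndrome. Comparing the plasmids within a line asks which transcripts of the host cell differ when EXACT1 is expressed. Totals ranged from 48475715 to 77100150 counts per library, and between 20586 and 28658 genes had at least 1 count.

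HepG2 and SH-SY5Y carried the markers of their tissue of origin. In HepG2, albumin (ALB) stood at 36395 ± 5141 CPM (SD, n = 6), alpha-fetoprotein (AFP) at 13294 ± 1928 CPM and transferrin (TF) at 14614 ± 837 CPM, and 26 of 28 hepatocyte markers exceeded 1 CPM. In SH-SY5Y, the neuronal growth protein STMN2 stood at 1673 ± 260 CPM (SD, n = 6), DBH, which makes noradrenaline, at 1159 ± 524 CPM, and the transcription factor HAND2 at 890 ± 43.2 CPM. There, 26 of 28 sympathetic neuroblast markers exceeded 1 CPM. Counts above 1 CPM were not specific to a line, with 20 of 28 hepatocyte markers in SH-SY5Y and 8 of 28 neuroblast markers in HepG2. The median hepatocyte marker stood at 951 CPM in HepG2 and 2.98 CPM in SH-SY5Y. The median neuroblast marker stood at 0.216 CPM in HepG2 and 207 CPM in SH-SY5Y. The marker lists of embryonic kidney and of fibroblasts had 3 of 20 and 8 of 24 members above 1 CPM in HepG2, and 5 of 20 and 21 of 24 in SH-SY5Y.

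**Figure D1:**
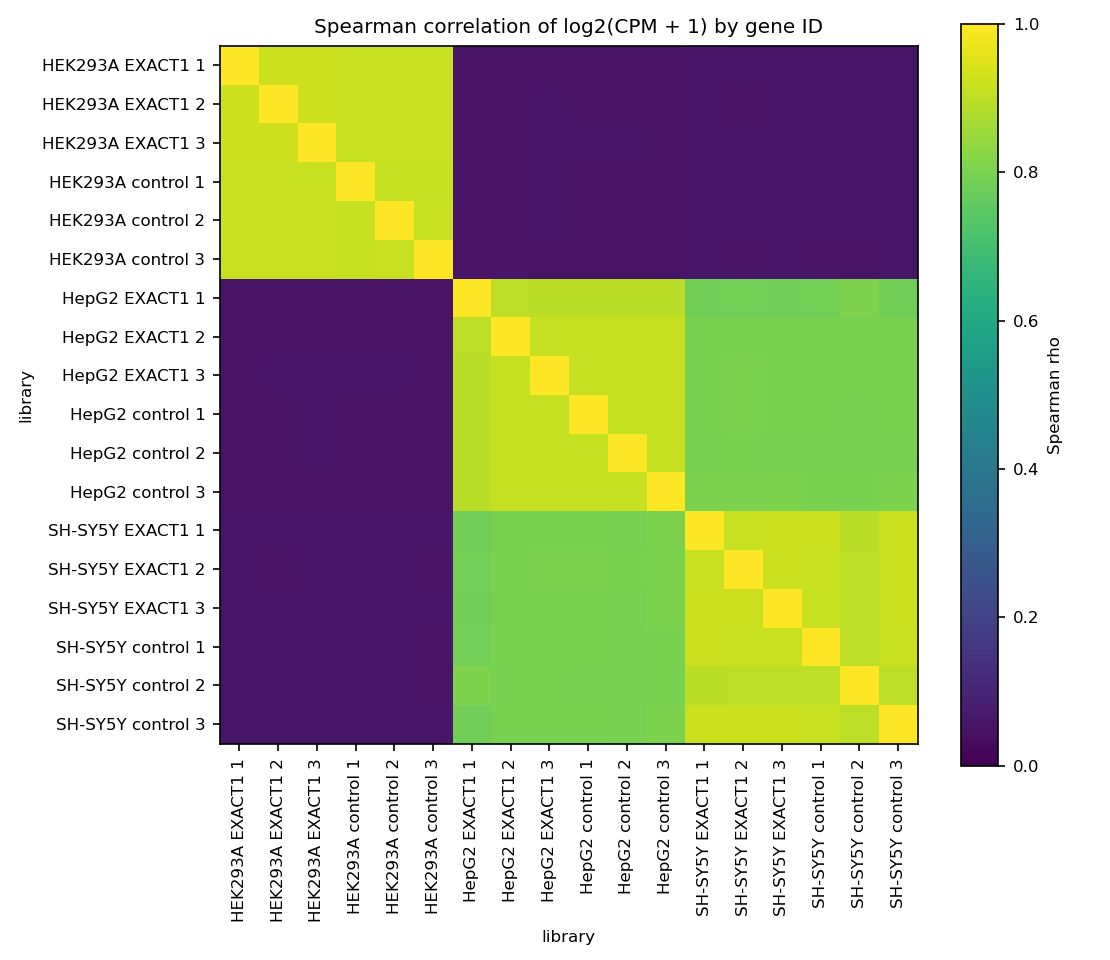
Spearman correlation of log2(CPM + 1) between the 18 libraries, matched by gene ID, with 1 square per pair and colour for rho. HEK293A libraries correlate with each other at 0.912 or more and with the other lines at 0.0589 or less, while HepG2 and SH-SY5Y correlate at 0.784 or more.

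In HEK293A, counts could not be assigned to named genes. Matched by gene ID, HEK293A libraries correlated with HepG2 at a mean Spearman rho of 0.0535 and with SH-SY5Y at 0.0563, against 0.797 between HepG2 and SH-SY5Y and 0.917 within HEK293A. Genes that every cell uses were at 0 in all 6 HEK293A libraries, among them the translation factor EEF1A1 (15542 ± 1524 CPM in HepG2, SD, n = 6), the glycolytic enzyme GAPDH (7770 ± 4432 CPM), the ribosomal protein RPLP0 and the tubulin TUBA1B. Of 6574 genes with over 500 counts in each of the other 12 libraries, 2555 (38.9%) were at 0 in all 6 HEK293A libraries. No HEK293A value is therefore given for a named gene. Among 22261 HEK293A rows tested, edgeR called 3, of which 2 were higher and 1 lower with EXACT1. There, 2014 rows had an unadjusted p under 0.05, a larger share than the 0.05 expected with no change. A replicate block left 0 calls and a mean CPM of at least 5 left 1. DESeq2 called 164, limma voom with sample weights called 3, and leaving out 1 library gave between 4 and 14, the most without EXACT1 replicate 1.

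In HepG2, no gene was called in the comparison of EXACT1 with control. The genes with the smallest p were 4 lower and 1 higher, and none passed (edgeR adjusted p = 0.792 for each). SMN2 (chromosome 5, 70049612 to 70078522), a near-identical copy of the motor neuron survival gene SMN1, stood at 15.5 ± 1.17 CPM with EXACT1 and 32.3 ± 2.26 CPM with control (SD, n = 3), a log2 fold change of -1.06 (SE 0.22). AGAP5 stood at 0.0453 ± 0.0491 against 1.35 ± 0.244 CPM (log2 fold change -4.78, SE 0.86), the pseudogene TCEA1P2 at 0.973 ± 0.416 against 6.79 ± 3.51 CPM (-2.80, SE 0.53), and ENSG00000288473 at 12.9 ± 1.95 against 5.91 ± 0.511 CPM (1.12, SE 0.24). MGAM, an intestinal maltase, had 0 counts in each EXACT1 library and between 15 and 20 in each control library, at least 4.59-fold lower against a floor of 3 counts per library. AGAP5, TCEA1P2 and SMN2 belong to families of similar sequence, and AGAP5 and MGAM overlap other annotated genes, so their counts are uncertain.

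AGO2 and DICER1, which encode core proteins of the miRNA pathway, were not called in HepG2. AGO2 stood at 51.6 ± 28.6 CPM with EXACT1 and 65.2 ± 3.47 CPM with control (SD, n = 3), a log2 fold change of -0.34 (SE 0.48, edgeR adjusted p = 0.792). DICER1 had a log2 fold change of -0.49 (SE 0.54). Without EXACT1 replicate 1, AGO2 had a log2 fold change of 0.06 with a 95% interval from -0.12 to 0.23, and DICER1 of -0.06 with an interval from -0.21 to 0.09.

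The count of 0 came from edgeR over 17139 HepG2 genes. Of these, 164 had an unadjusted p under 0.05, a smaller share than the 0.05 expected with no change. DESeq2 called 11 genes, among them AGAP5 (adjusted p = 1.89e-05) and TCEA1P2 (adjusted p = 0.0011), and limma voom with sample weights called 2, SMN2 and ENSG00000288473. EXACT1 replicate 1 lay far from its group, with a mean correlation to it of 0.943 against 0.969 to 0.996 in the other HepG2 libraries. Without it, edgeR called 2 of 17832 genes, both lower: SMN2 (log2 fold change -1.03, SE 0.10, adjusted p = 0.0166) and the pseudogene SMG1P6 (-3.07, SE 0.36, adjusted p = 0.0403), whose parent gene SMG1 differed by -0.10 on the log2 scale of mean CPM. Simulated counts of these 5 libraries, with 200 genes changed 2-fold or 4-fold and 40 changed 1.5-fold, gave 20 calls among unchanged genes. These came beside 80 and 95 recovered genes of those changed 2-fold and 4-fold, at a looser cutoff than that of 2 calls. Whether either call is false therefore stays open. The share of genes whose 95% interval lay within 1 log2 unit of 0 was 26.0% with all 6 libraries and 68.3% without that library.

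Of the 28 gene lists, 2 were called in HepG2, both higher with EXACT1, and both followed 1 library. None was called with an estimated correlation or with fry, where the lowest adjusted p of any list was 0.787 and 0.567. The cytosolic ribosomal proteins had a median log2 fold change of 0.67, with 76 of 77 members above 0, at an adjusted p of 1.69e-11 (camera, preset correlation). RPL3 stood at 2721 ± 1510 against 1865 ± 27.1 CPM and RPLP0 at 2358 ± 1520 against 1471 ± 24.3 CPM (SD, n = 3). The nuclear genes of the respiratory chain, which carries out oxidative phosphorylation, had a median of 0.47, with 65 of 70 members above 0 and an adjusted p of 3.68e-08. Ribosomal protein genes took 9.70% of counts in EXACT1 replicate 1 and between 4.54% and 4.69% in the other 5 HepG2 libraries. Without that library the medians were -0.0075 for the ribosomal proteins and 0.01 for the respiratory chain.

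Lists tied to miRNAs and to sensing of foreign nucleic acid were not called in HepG2. Median log2 fold changes were -0.26 for the miRNA pathway, -0.33 for let-7 targets, -0.24 for targets of the miR-17 family, 0.35 for interferon-stimulated genes, 0.17 for nucleic acid sensors, -0.01 for NF-kB targets, -0.17 for p53 targets and 0.24 for the integrated stress response. Among their abundant members, HMGA2, a let-7 target, had a log2 fold change of -0.32 (SE 0.42), GDF15 of 0.67 (SE 0.41) and ATF4 of 0.45 (SE 0.33). Without EXACT1 replicate 1, 4 lists were called at the preset correlation: interferon-stimulated genes (median 0.14), the integrated stress response (0.06), DNA replication (0.06) and mitochondrial transcripts (-0.07). None was called by camera with an estimated correlation, where the lowest adjusted p was 0.966. No list member was called among 748 tested, nor adjusted over the list alone, and without that library 676 of 757 members had a 95% interval within 1 log2 unit of 0.

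**Figure D2:**
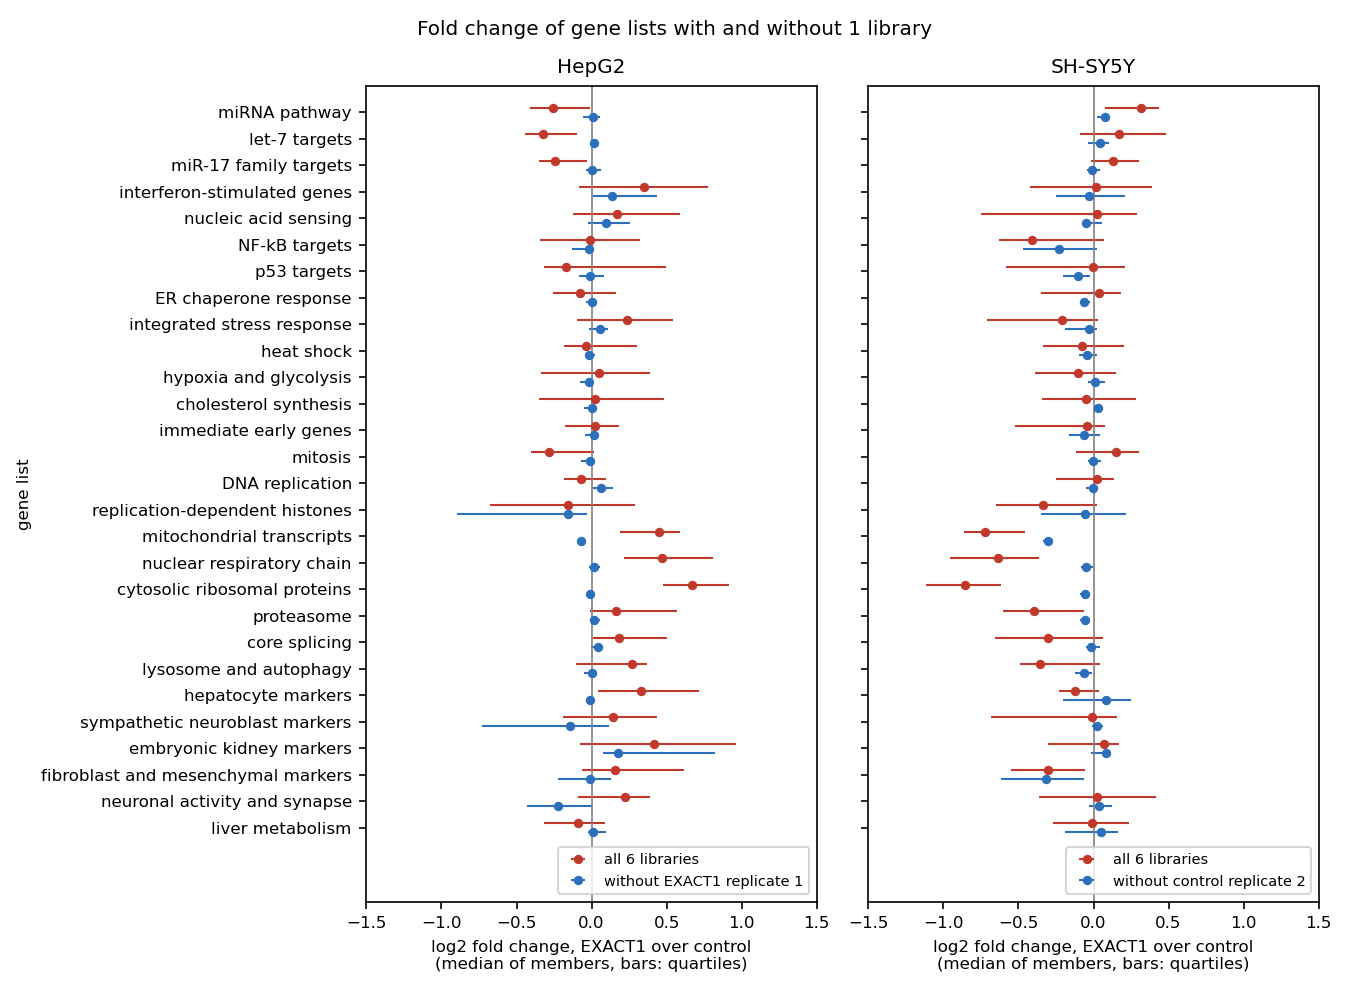
Median log2 fold change, EXACT1 over control, of the 28 gene lists in HepG2 and SH-SY5Y, with bars from the lower to the upper quartile of members. Red points use all 6 libraries and blue points leave out 1 library. The ribosomal proteins lie at 0.67 and -0.86 in red and at -0.0075 and -0.06 in blue.

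In SH-SY5Y, no gene was called either. The 5 genes with the smallest p were 3 higher and 2 lower, and none passed (edgeR adjusted p = 0.796 for each). SCN8A (chromosome 12, 51590266 to 51812864), which encodes a neuronal sodium channel, stood at 16.6 ± 2.03 CPM with EXACT1 and 5.42 ± 0.746 CPM with control (SD, n = 3), a log2 fold change of 1.61 (SE 0.23). ENTPD1-AS1 (chromosome 10, 95753206 to 96090238), annotated antisense to the ectonucleotidase gene ENTPD1, stood at 4.66 ± 0.259 against 28.8 ± 15.2 CPM (-2.63, SE 0.47). GDF1, which overlaps CERS1 on the same strand, stood at 3.17 ± 1.09 against 9.94 ± 0.895 CPM (-1.65, SE 0.32), ENSG00000260342 at 17.2 ± 7.93 against 2.90 ± 1.22 CPM (2.57, SE 0.51), and the readthrough transcript TBC1D3P1-DHX40P1 at 0.522 ± 0.168 against 0.0507 ± 0.0101 CPM (3.33, SE 0.61). Each of these overlaps another annotated gene, SCN8A only on the opposite strand, so their counts are uncertain.

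In SH-SY5Y, AGO2 stood at 98.1 ± 11.3 CPM with EXACT1 and 69.8 ± 29.3 CPM with control (SD, n = 3), a log2 fold change of 0.49 (SE 0.36, edgeR adjusted p = 0.796). DICER1 had a log2 fold change of 0.56 (SE 0.36). Without control replicate 2, AGO2 had a log2 fold change of 0.18 with a 95% interval from -0.04 to 0.40, and DICER1 of 0.28 with an interval from -0.15 to 0.70.

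The count of 0 came from edgeR over 19853 SH-SY5Y genes. Of these, 200 had an unadjusted p under 0.05, a smaller share than the 0.05 expected with no change. DESeq2 called 6 genes, among them SCN8A (adjusted p = 0.0028), ENTPD1-AS1 (adjusted p = 0.000537) and ENSG00000260342 (adjusted p = 0.0015), and limma voom with sample weights called 1, ENTPD1-AS1. Control replicate 2 lay far from its group, with a mean correlation to it of 0.954 against 0.972 to 0.996 in the other SH-SY5Y libraries. Without it, edgeR called 1 of 20718 genes, ENTPD1-AS1 (log2 fold change -3.00, SE 0.13, adjusted p = 4.58e-05), and SCN8A had a log2 fold change of 1.56 (SE 0.18, adjusted p = 0.0597). Simulated counts of these 5 libraries, with 200 genes changed 2-fold or 4-fold and 40 changed 1.5-fold, gave 21 calls among unchanged genes. These came beside 68 and 94 recovered genes of those changed 2-fold and 4-fold, at a looser cutoff than that of 1 call. Whether the call of ENTPD1-AS1 is false therefore stays open. The share of genes whose 95% interval lay within 1 log2 unit of 0 was 29.4% with all 6 libraries and 63.3% without that library.

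**Figure D3:**
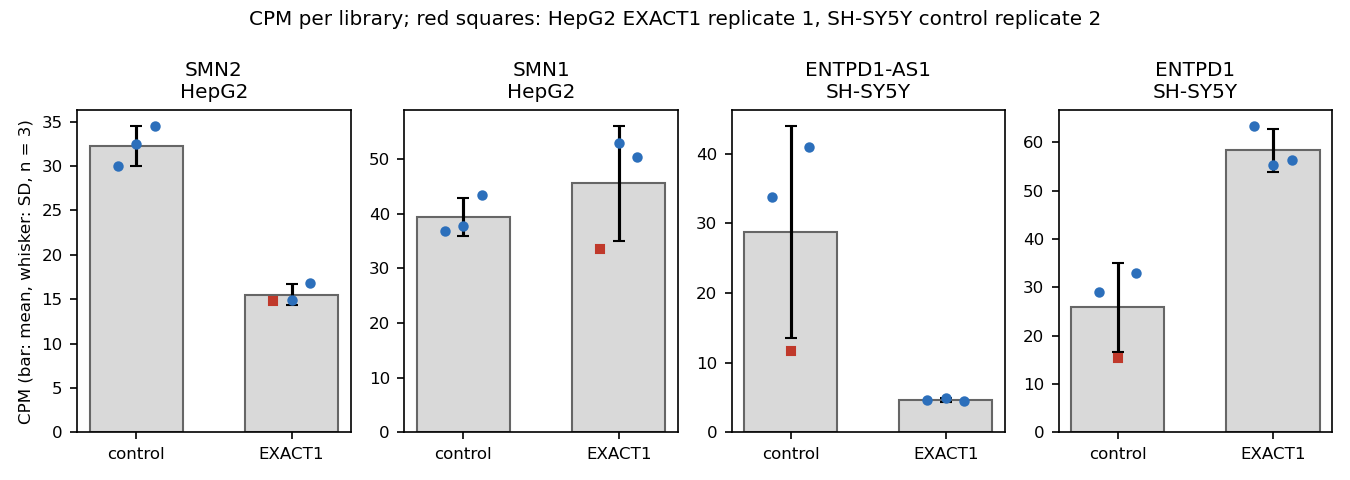
CPM of SMN2 and SMN1 in HepG2 and of ENTPD1-AS1 and ENTPD1 in SH-SY5Y, per library, with bars for the mean and whiskers for the SD (n = 3). Red squares mark HepG2 EXACT1 replicate 1 and SH-SY5Y control replicate 2. SMN2 lies at 15.5 CPM with EXACT1 and 32.3 with control, and SMN1 at 45.6 and 39.4, while ENTPD1-AS1 lies at 4.66 and 28.8, and ENTPD1 at 58.3 and 25.8.

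Of the 28 gene lists, 8 were called in SH-SY5Y at the preset correlation, 7 lower and 1 higher with EXACT1. None was called with an estimated correlation or with fry, where the lowest adjusted p of any list was 0.886 and 0.830. Medians of the lower lists were -0.86 for cytosolic ribosomal proteins (77 of 77 members below 0, camera adjusted p = 5.34e-16 at the preset correlation), -0.72 for mitochondrial transcripts (13 of 13), -0.64 for the nuclear respiratory chain (67 of 70), -0.39 for the proteasome (25 of 31), -0.36 for lysosome and autophagy genes (17 of 25), -0.30 for core splicing factors (24 of 33) and -0.21 for the integrated stress response (19 of 27). The miRNA pathway had a median of 0.32, with 20 of 26 members above 0 and an adjusted p of 0.0155. RPS2 stood at 1433 ± 70.2 against 3221 ± 3044 CPM and MT-CO2 at 3155 ± 225 against 5202 ± 2388 CPM (SD, n = 3), and the large SDs came with control replicate 2. Ribosomal protein genes took 12.8% of counts in control replicate 2 and between 5.37% and 5.80% in the other 5 SH-SY5Y libraries.

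Without control replicate 2, the ribosomal proteins had a median of -0.06, the respiratory chain of -0.05, the proteasome of -0.06, lysosome and autophagy genes of -0.06, core splicing factors of -0.02, the integrated stress response of -0.03 and the miRNA pathway of 0.08. The 13 transcripts of the mitochondrial genome kept a median of -0.30, and MT-CO2 had a log2 fold change of -0.29 (SE 0.11). At the preset correlation 8 lists were again called, with p53 targets (-0.10) and the ER chaperone response (-0.06) in place of splicing and the integrated stress response. None was called by camera with an estimated correlation, where the lowest adjusted p was 0.928. Control replicate 1 had 3.44% of counts from mitochondrial transcripts, above the 2.12% of control replicate 3 and the 2.10% to 2.45% of the EXACT1 libraries. No list member was called among 770 tested, nor adjusted over the list alone, and without that library 638 of 775 had a 95% interval within 1 log2 unit of 0. With all libraries, let-7 targets had a median of 0.17, miR-17 family targets of 0.13, interferon-stimulated genes of 0.02, nucleic acid sensors of 0.02, NF-kB targets of -0.41 and p53 targets of -0.0037, and none was called.

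No gene was called for a mean change over HepG2 and SH-SY5Y, and none for a difference between them, among 22009 genes in edgeR. Unadjusted p was under 0.05 for 577 genes in the first test and for 1907 in the second. The first share is below the 0.05 expected with no change, and the second is above it. For the difference, the count was 766 of 23089 genes without HepG2 EXACT1 replicate 1 and 672 of 23009 without SH-SY5Y control replicate 2. Without both it was 1029 of 22857. Each of these shares is below 0.05, so the excess depended on these 2 libraries. DESeq2 called 22 and 26 genes, and limma voom with sample weights called 2 (ZNF225-AS1 and ENSG00000276115) and 1 (ZNF225-AS1). Without HepG2 EXACT1 replicate 1 and SH-SY5Y control replicate 2, edgeR called 1 gene for the mean, ENSG00000286403 (-3.31, SE 0.27, adjusted p = 0.0375), and 2 for the difference, ENSG00000286403 (adjusted p = 0.0454) and ZNF225-AS1 (adjusted p = 0.0474). ENSG00000286403 had a log2 fold change of -0.17 in HepG2 alone with all libraries. Its difference of HepG2 minus SH-SY5Y was 6.49, so its mean reflects mainly SH-SY5Y and not a change in both lines. ENSG00000286403 did not pass the count filter of SH-SY5Y alone, nor ZNF225-AS1 that of HepG2 alone, so their fold changes there rest on few counts. Across 11655 genes, log2 fold changes of the lines correlated at a Pearson r of -0.83 with all libraries and 0.04 without those 2 libraries, and genes are not independent replicates.

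No 7-base word in 3' UTRs was linked to lower expression with EXACT1 in both lines. With all libraries, 46 of 16384 words had a negative slope past the threshold in HepG2 and 648 in SH-SY5Y, and 0 were shared, while 1268 and 29 words had a positive slope past it. Among words with a negative slope, the smallest p was that of TTTTGTT in HepG2 (slope -0.05) and TACAGGC in SH-SY5Y (slope -0.07). Without HepG2 EXACT1 replicate 1, 1 word passed in HepG2, TATCGTA, present in 183 genes with a median log2 fold change of -0.03 (slope -0.17, SE 0.03, adjusted p = 0.033), and with all libraries it passed too (slope -0.10, SE 0.03, adjusted p = 0.0258). At a mean CPM of at least 5 with all libraries, TATCGTA did not pass in HepG2 (word regression, slope -0.02, adjusted p = 0.574). The slope of TATCGTA in SH-SY5Y without control replicate 2 was 0.02, and there 0 words passed.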

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

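The tests of the row offset and of cell identity in HEK293A, of the library difference common to both lines, of transcript length and GC content, of depth, of the EXACT1 plasmid, and of the gene pairs were chosen only after the results they concern had been seen.

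The change with EXACT1 differed between HepG2 and SH-SY5Y for 9 of 28 gene lists, by camera at the preset correlation on the difference of the lines. Medians of HepG2 minus SH-SY5Y were 1.09 for cytosolic ribosomal proteins, 1.00 for mitochondrial transcripts, 0.89 for the nuclear respiratory chain, 0.53 for the proteasome, 0.53 for lysosome and autophagy genes, 0.52 for the integrated stress response, 0.40 for core splicing, -0.51 for mitosis and -0.76 for the miRNA pathway, in log2 units. None differed with an estimated correlation (lowest adjusted p = 0.727). Without HepG2 EXACT1 replicate 1 and SH-SY5Y control replicate 2, 6 lists differed at the preset correlation and 0 with an estimated one (lowest adjusted p = 0.839), and no list with a difference called there had a median beyond 0.20 in size.

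HepG2 EXACT1 replicate 1 and SH-SY5Y control replicate 2 deviated from their groups in nearly the same genes, with a correlation of 0.876 across 11472 genes, against -0.05 to 0.03 between HepG2 control and SH-SY5Y EXACT1 libraries. The EXACT1 plasmid as the cause is argued against, since 1 of the libraries is a control and the change of HepG2 EXACT1 replicate 1 correlated at only 0.0439 with that of EXACT1 replicates 2 and 3. Depth is argued against, since among genes with over 500 counts in each library of a line, where sampling noise is small, the deviations still had an SD of 1.20 log2 units in HepG2 and 1.13 in SH-SY5Y, against 0.13 to 0.16 and 0.14 to 0.19 in the libraries of the other plasmid. Regression on transcript length and GC content left 38.7% of the variance in HepG2 and 40.6% in SH-SY5Y, with short and GC-rich transcripts higher, which is consistent with a length- and GC-dependent difference in RNA or library preparation. What produced it stays open, since RNA quality values and preparation batches are not given in the sources used here, and no biological explanation other than the plasmid was tested.

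HEK293A counts did not match the gene IDs of their rows, and 42 of the 100 genes most abundant in the other lines were at 0 in all 6 HEK293A libraries. This argues against a property of HEK293A cells, since these genes serve every cell. HEK293A values were compared with the other lines in 117 windows of 500 rows. In 100% of them, the correlation was higher at some offset within 40 rows than at as many offsets 1000 rows away. Against unrelated rows this held in 60 windows (median at the best offset 0.117), and for shuffled SH-SY5Y values against HepG2 in 57. The median HEK293A correlation was 0.478 at the best offset and 0.0290 as recorded. Reading rows at these offsets raised the share of protein-coding genes among the 1000 most counted rows by 30.6 percentage points, from 41.7% to 72.3%, against 97.8% in SH-SY5Y. Random offsets gave at most 40.5%. The best offsets were chosen to follow expression in the other lines, whose most counted rows are nearly all protein-coding. The rise may partly follow from that choice and is not separate support. Values moved by a few rows against the IDs may account for the mismatch, and the offset varied from -16 to 17 rows, so no names were reassigned.

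SMN2 in HepG2 and ENTPD1-AS1 in SH-SY5Y were the clearest lower genes without the outlying libraries, and each has a partner that was higher. SMN1 had a log2 ratio of 0.39, and the sum of SMN2 and SMN1 changed by -0.087, against -1.03 for SMN2. ENTPD1 had a ratio of 0.91, and the sum with ENTPD1-AS1 changed by -0.12, against -3.00 for ENTPD1-AS1. A fall of SMN2 or ENTPD1-AS1 alone would also change the sum by less than that gene, so the sums alone cannot decide. Such a fall would leave the partner unchanged. Without the outlying libraries, SMN1 stood at 51.6 ± 1.77 CPM with EXACT1 (SD, n = 2) and 39.4 ± 3.502 CPM with control (n = 3). ENTPD1 stood at 58.3 ± 4.46 (n = 3) against 31.01 ± 2.83 CPM (n = 2). These values argue against a fall of SMN2 or ENTPD1-AS1 alone. With all libraries, SMN1 with EXACT1 overlapped control, at 45.6 ± 10.6 CPM. Reads assigned differently between near-identical or overlapping genes may account for both pairs. The choice of transcript, or a lowering by EXACT1 with a separate rise of the partner, stays open. The fall of SMN2 was not seen in SH-SY5Y, where its log2 ratio was 0.11 with all libraries and -0.07 without control replicate 2. Whether genes with small p overlap other genes more often was not decided, with odds ratios of 1.33 (95% interval 0.829 to 2.22) in HepG2 and 1.19 (0.748 to 1.95) in SH-SY5Y.

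The 6 libraries of a line can be split 3 against 3 in 10 ways, the real grouping included, too few for a share under 0.05. For genes, the real count was 3 in HEK293A (highest other 18) and 0 in HepG2 and in SH-SY5Y (highest other 0 in both), and a count of 0 is reached by any split. For lists, the real count was 2 in HepG2 (highest other 9) and 8 in SH-SY5Y (highest other 12). For words with a negative slope, it was 46 in HepG2 (highest other 78) and 648 in SH-SY5Y (highest other 1822), with the direction of the other splits set by the order of libraries. Splits with several times the real count were seen for genes in HEK293A and lists in HepG2. Such splits can come from a structure of the samples other than the plasmid, which was not tested. The 13 calls among unchanged rows in simulated HEK293A counts came beside recovered planted rows, at a looser cutoff, and do not bear on these splits. For the tests over 2 lines, the real count was 0, which any split reaches, so the 60 splits drawn, the real one included, could decide nothing (highest other 4 for the mean and 2 for the difference).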

How the results depend on the processing

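The tests over 2 lines and the word regressions without the outlying libraries were chosen after seeing the data. Genes called in HEK293A numbered 3, and 17 with no filter, 1 at a mean CPM of at least 5, 164 with DESeq2 and 20 in the fit of all 18 libraries, with a range of 4 to 14 when 1 library was left out. The 0 calls in HepG2 became 11 with DESeq2 and 2 with limma voom with sample weights, with a range of 0 to 2 when 1 library was left out. The 0 calls in SH-SY5Y became 6 with DESeq2, 1 with limma voom with sample weights and 2 in the fit of all 18 libraries, which takes in the mismatched HEK293A rows, with a range of 0 to 1 when 1 library was left out. For the mean over 2 lines, the count of 0 became 22 with DESeq2, 2 with voom and 1 without both outlying libraries, and for the difference it became 26, 1 and 2. The other scalings in edgeR left these counts as they were, and 10 of 236 values of named genes under an alternative changed sign, none of them called.

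Lists called in HepG2 numbered 2, and 0 with an estimated correlation, 0 with fry and 7 at a mean CPM of at least 5, with a range of 2 to 7 when 1 library was left out. The median of their ribosomal proteins went from 0.67 to -0.0075 without EXACT1 replicate 1, so that 1 library set its direction, and leaving out any 1 library gave a range from -0.0075 to 0.92. Lists called in SH-SY5Y numbered 8, and 0 with an estimated correlation and 0 with fry, with a range of 6 to 9. Words numbered 46 in HepG2, and 124 with 6 bases, 173 at a mean CPM of at least 5 and 1 without the outlying library. They numbered 648 in SH-SY5Y, and 103, 4670 and 0 under the same settings, and 27 with the 3' UTR of the longest coding sequence. Apart from the outlying libraries, the cause of these shifts was not tested.

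Replicate numbers did not pair the samples: libraries with the same number deviated together at r of 0.02, 0.00 and -0.01 in HEK293A, 0.01, -0.02 and 0.03 in HepG2 and 0.24, 0.09 and 0.03 in SH-SY5Y, and not every library correlated best with its own number. A replicate block gave 0 calls in HEK293A, HepG2, SH-SY5Y and both tests over 2 lines, 10 lists in HepG2 and 8 in SH-SY5Y. The tests over 3 lines and the HEK293A lists were not run, because the HEK293A IDs did not match. With 6 libraries, simulations of HepG2 and SH-SY5Y recovered 0 of 100 genes changed 2-fold in both and 14 and 20 of 100 changed 4-fold, so the counts of 0 there exclude neither size. With 5 libraries, without the outlying ones, they recovered 80 and 68 of 100 changed 2-fold, where the real data gave 2 calls and 1 call. That recovery came with many genes changed at once, at a looser cutoff than that of the real data. It covers only genes with a mean CPM of at least 1. The few real calls therefore do not exclude 2-fold changes.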

Other observations

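The test for a shared 3' UTR word was fixed before the fits without the outlying libraries were seen, and TATCGTA was looked at only after it had passed.

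Several groups of genes showed no call in either line. Without the outlying library of each line, cholesterol synthesis had a median log2 fold change of -2.3e-05 in HepG2 and 0.03 in SH-SY5Y, hypoxia and glycolysis genes of -0.02 and 0.01, heat shock genes of -0.02 and -0.05, immediate early genes of 0.02 and -0.06 and mitosis genes of -0.01 and -0.0019. Hepatocyte markers had a median of -0.01 and liver metabolism genes of 0.01 in HepG2, while neuroblast markers had a median of 0.03 and synaptic genes of 0.04 in SH-SY5Y. Replication-dependent histones, whose mRNAs lack a poly(A) tail, had medians of -0.16 and -0.06, embryonic kidney markers of 0.18 and 0.08, and fibroblast markers of -0.01 and -0.32. None of these lists was called with or without the library (camera, preset correlation).

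Transcripts of hepatocytes were counted at low levels in SH-SY5Y. ALB stood at 104 ± 10.9 CPM (SD, n = 6), 0.285% of its HepG2 level, and the other 7 liver genes examined, among them AFP, TF and APOB, at 0.158% to 0.308%. In the other direction, the neuroblast genes examined stood in HepG2 at 0.0455% (HAND2) to 0.958% (CHGB) of their SH-SY5Y level. Other members of the neuroblast list, such as TUBB3 and DDC, lay outside this range. The genes examined were chosen after their values were seen, and no explanation was tested.

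The hypothesis of a 3' UTR word lowered in both lines by the EXACT1 miRNA was tested, since EXACT1 might act on transcripts of the host through its seed, whose sequence is not given in the sources used here. Without the outlying libraries, 0 words of 7 bases had a negative slope past the threshold in both lines. A planted word with a log2 change of -0.2, in 758 genes in HepG2 and 515 in SH-SY5Y, was recovered in shuffled fold changes of each. The 1 word that passed in HepG2, TATCGTA, had 10 of its 183 genes below a log2 fold change of -1. With all libraries it passed too, with a slope of -0.10 (word regression, adjusted p = 0.0258). At a mean CPM of at least 5 with all libraries it did not pass (slope -0.02, adjusted p = 0.574). A smaller effect, or one on few genes, stays open.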
